A study of Homo sapiens with 6 samples.

How the data were processed

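RNA was measured on Affymetrix HG-U133 Plus 2.0 arrays in sorted NALM-6 leukemia cells, 3 samples from untreated mice and 3 from mice given Ara-C for 2 days. Total RNA had been isolated with a column kit and labelled with biotin after 1 cycle of amplification, per the labels' protocols. The deposited values are 1 table of log2 signals, with 1 column per array and 54675 probe sets. They were made with Affymetrix Expression Console, per the submitters' processing notes, and the version and summary algorithm are not given in the sources used here. That the authors' values are on a log2 scale was inferred from their range, 1.66 to 13.98 with array medians of 4.82 to 4.87, and how they were normalized between arrays is not stated. Some summary algorithms for such arrays shrink large fold changes, and whether this one does is not known here. Detection calls and scanner intensities were not used here, so a signal cannot be said to lie above background, and a fold from a low signal is a value on this scale only.

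Each column was matched to its sample by name and each sample to its group by its treatment label. No pair of arrays held identical values. The 62 control probe sets stayed out of the tests. Of the others, 41091 are paired with 1 gene in the platform annotation, 1801 with several, and 11721 are not listed there and stay unnamed. Of those with 1 gene, 41043 matched a gene of the RefSeq table by Entrez identifier, and 0 symbols changed. No genomic coordinates were used, since the build behind the annotation is not given in the sources used here. For each gene the probe set with the highest mean over all 6 arrays was taken, which gave 19775 genes. CCL3, a gene fixed for naming in advance, has no probe set paired with it alone and so has no value among the genes.

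The values were tested as deposited, with no further scaling. Residual cells were compared with untreated cells in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided), with no covariate, 4 residual and 4.78 prior degrees of freedom. Benjamini-Hochberg adjustment ran over all genes, with a threshold of 0.05. Changes are residual minus untreated on the log2 scale, with the standard error (SE) of that fit and 95% intervals of its moderated distribution, and values beside ± are SDs of 3 arrays. The same fit was run on all 54613 probe sets that are not controls, where 5091 passed, 3210 higher and 1881 lower. Before the data were examined, 30 gene lists were fixed from general knowledge of cytarabine, B cell leukemia and bone marrow. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists, and again with an estimated correlation and with fry. A list member without a probe set of its own was not analysed. Members were also counted with the adjustment run over each list alone.

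The genes named in the text were taken by a rule fixed in advance. It took GDF15, CCL3 and TGFB1, which were already known from the study and were also on some of the gene lists. Their naming is therefore no independent finding. CDKN1A, MDM2, MKI67 and CXCR4 were always taken as well. It took the 6 largest rises and 6 largest falls among passing genes whose groups do not overlap and whose brighter group has a mean above the median of all genes. It took up to 2 passing members in each direction of each primary list (p53, S phase, mitosis, TGF-beta, secreted factors, adhesion, early B cell), and 1 in each direction of the other lists. For lists of other cell types it also took the brightest member. This gave 67 genes. Members named beyond it, because a list had few changed genes, were chosen after their values were seen.

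The fit was tested on simulated data for this comparison, 20 runs over 19775 genes with 200 of them changed. It recovered 50.7% of genes changed by 0.5 on the log2 scale, 92.3% of those changed by 1 and 99.5% of those changed by 2, and 4.14% of its calls were false. The real comparison had 2710 genes past the threshold, far more than the 200 simulated, so these shares need not hold for it. A list shifted by 0.3 was called in 20 of the runs with the preset correlation and in 19 with an estimated one. Of 25 unshifted lists, camera called 0 per run. The genes were simulated independently, while the correlation estimated for the p53 list in the real data was 0.30. These runs thus cannot show how the list calls hold when genes are correlated. With 3 arrays against 3, an exact permutation test cannot give a p under 0.1.

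Alternatives tried were a replicate block, quantile normalization, centring on array medians, leaving out the 50% of probe sets with the lowest mean, a variance trend with robust moderation, other choices of probe set per gene, stricter thresholds, other list tests, and leaving out each array in turn. Lists without the members they share with the p53 list were added after seeing the data. The tests were also run on the other splits of the 6 arrays. The shared replicate numbers were not taken as pairs.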

Results

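NALM-6 is a human cell line of precursor B cell acute lymphoblastic leukemia. Here NALM-6 cells carrying GFP, a fluorescent protein that allows sorting, had been engrafted in mice. The leukemia cells were recovered by flow sorting from untreated mice and from mice given Ara-C for 2 days, whose remaining leukemia cells are called residual cells below. Ara-C (cytarabine) is a nucleoside analog that stops DNA synthesis and is used against acute leukemia. The RNA of each sample was measured on 1 human expression array, with 3 arrays per group and 6 in all, and this number of arrays limits the precision. The labels call the samples of a group biological replicates but do not tie them to single mice, so the p-values measure only the spread between these samples, part of which may be technical.

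The arrays were alike in overall signal, with a median log2 signal of 4.82 to 4.87. Across probe sets, which are not independent replicates, Pearson's r was 0.995 to 0.997 between arrays of a group and 0.989 to 0.992 between the groups. The first principal component held 66.1% of the variance and separated residual from untreated cells. Some controls differed as well. The control probe set for the 5' end of 18S ribosomal RNA read 12.27, 12.42 and 12.40 in untreated cells and 12.42, 13.09 and 12.82 in residual cells (log2 signal, replicates 1 to 3). The 3' minus 5' difference of the GAPDH controls, a sign of RNA integrity, was 0.40, 0.31 and 0.33 in untreated cells and 0.41, 0.43 and 0.42 in residual cells (log2). That difference of the ACTB controls was 2.65, 2.35 and 2.26 in untreated cells and 2.41, 2.26 and 2.43 in residual cells. Only the GAPDH difference divided the arrays by group, narrowly, and this division is also that of the comparison below.

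The design gives 1 comparison, residual against untreated cells, which asks how leukemia cells that withstand the first days of chemotherapy differ from unexposed ones. The series title places it in work on how leukemia cells reshape their niche under therapy. Rises and falls below are differences between these 2 groups of cells, and were not followed within cells. After 2 days of Ara-C, 32 of 39 p53 target genes rose, among them CDKN1A, which encodes the cell cycle inhibitor p21 (9.98-fold), and GDF15, a secreted stress cytokine (33.6-fold on 1 of its 3 probe sets, but a log2 change of -0.02 under another choice of probe set). Rises were also seen in 16 of 35 interferon-stimulated genes, 12 of 26 NF-kappaB targets and 12 of 29 immediate early and handling stress genes. In addition, 10 of 31 lysosome genes and 10 of 21 MHC genes rose. Falls were seen in 11 of 29 genes of MYC and ribosome biogenesis and 8 of 55 genes of G2 and mitosis, and in 4 and 2 of them without untreated replicate 2. The rises among lysosome and MHC genes numbered 6 and 5 without Ara-C replicate 2. These lists passed limma's camera with a preset correlation between genes, and each lost its call with an estimated correlation (adjusted p from 0.181 to 0.46). B cell genes moved both ways, with a rise of MS4A1 (CD20) and a fall of IGLL1, a part of the surrogate light chain of early B cells.

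Of 19775 genes tested with limma, 2710 passed an adjusted p of 0.05, 1863 of them higher and 847 lower in residual cells. Among the 5299 genes with an untreated mean log2 signal above 8, 573 were higher and 491 lower. Most of the excess of rises over falls thus lay in the 14476 genes at or below 8, which are also most of the genes tested. Changes of at least 2-fold were 257 rises and 6 falls, and the falls numbered 9 without untreated replicate 1, 10 without untreated replicate 3 or Ara-C replicate 1, and 2 without Ara-C replicate 3. In 6554 genes (33.1%) the 3 arrays of a group lay wholly above or below those of the other, against 10% by chance, and the median change of all genes was -0.01 on the log2 scale. The number of genes past the threshold was 1662 without untreated replicate 2 and 1589 without Ara-C replicate 2. Falls depended on single arrays more, with 346 and 548 of them without untreated replicates 2 and 3, and 336 and 439 without Ara-C replicates 2 and 3.

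**Figure D1:**
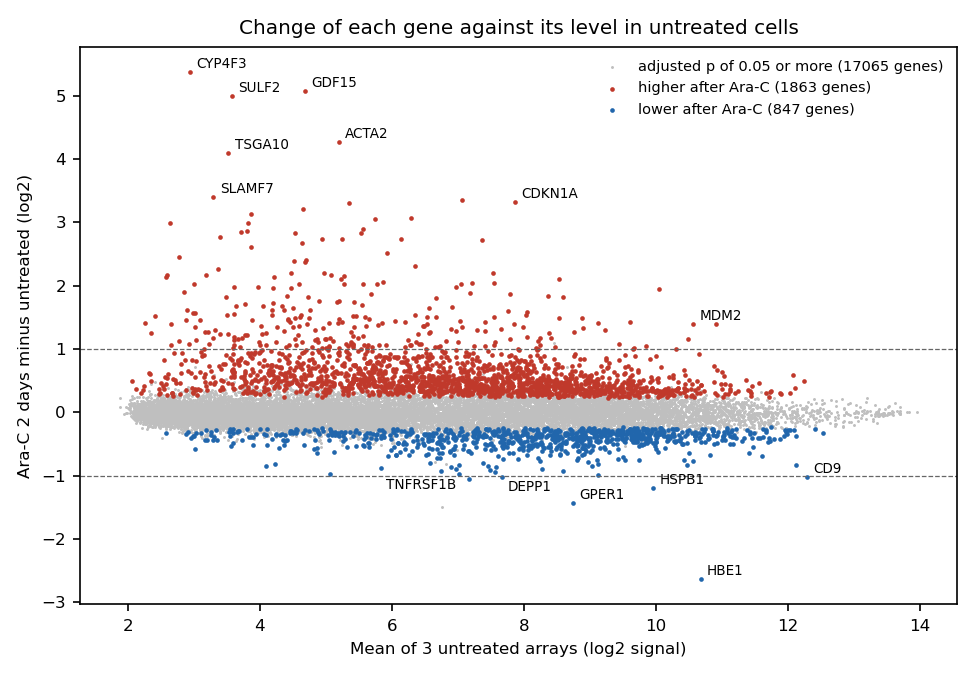
Change of each gene (Ara-C 2 days minus untreated, log2) against its mean log2 signal on the 3 untreated arrays, with genes past an adjusted p of 0.05 in limma in red (1863 higher) and blue (847 lower), and dashed lines at 2-fold. The 257 rises of at least 2-fold lie mostly among genes of low signal in untreated cells, and 6 genes fell by as much.

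The largest rises were those of CYP4F3, a fatty acid hydroxylase (41.4-fold, 95% interval 34.7 to 49.3), GDF15 (33.6-fold, 27.1 to 41.7) and SULF2, a sulfatase that trims cell surface heparan sulfate (31.9-fold, 25.5 to 40.0). ACTA2, smooth muscle actin, rose by 19.3-fold (14.8 to 25.2), TSGA10, a gene of the testis, by 17.1-fold (13.7 to 21.3), and SLAMF7, a receptor of plasma cells and other lymphocytes, by 10.6-fold (8.59 to 13.1). The rise of GDF15 rested on 1 of its 3 probe sets, and a probe set of the kind made for a single transcript gave -0.02 on the log2 scale. ACTA2 likewise passed on 1 of its 3 probe sets, and TSGA10 on 2 of 4, the lowest giving -0.21. The largest falls were those of HBE1, the embryonic globin gene (6.18-fold lower, log2 change -2.63, SE 0.25), and GPER1, a membrane estrogen receptor (2.70-fold lower, -1.43, SE 0.08). HSPB1, a small heat shock protein (-1.19, SE 0.32), TNFRSF1B, a TNF receptor (-1.05, SE 0.15), CD9, a tetraspanin of the cell surface (-1.02, SE 0.07), and DEPP1, a FOXO target (-1.02, SE 0.11), made up the rest. These changes all passed in limma, with adjusted p-values from 1.15e-07 for CYP4F3 to 0.0377 for HSPB1. CD9 passed on 2 of its 3 probe sets and DEPP1 on 1 of 2, the weakest giving -0.04 and -0.16. The call of HSPB1 was lost without any array but untreated replicate 1, with changes of -0.92 to -1.31 (adjusted p from 0.0626 to 0.121 in limma), and also with a variance trend and robust moderation (0.162).

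p53 target genes gave the clearest shift. Of 39 measured, 32 rose and 7 did not pass, and adjusted over the list alone 32 rose and 1 fell. The log2 signal of CDKN1A went from 7.86 ± 0.11 to 11.18 ± 0.16 (SD, n = 3 arrays each), a change of 3.32 (SE 0.10). MDM2, the ubiquitin ligase that degrades p53, rose by 1.39 (SE 0.09), with 8 of its 10 probe sets past the threshold. The changes of the 10 probe sets ranged from 0.17 to 3.92. TP53INP1, a p53 partner in stress responses, rose by 3.35 (SE 0.13), on 1 of its 3 probe sets. The median change of the list was 1.36. The list passed limma's camera at an adjusted p of 2.42e-28 with the preset correlation between genes, and had an adjusted p = 0.192 with an estimated correlation.

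Of 26 measured BCL2 family and apoptosis genes, 7 rose, 1 fell and 18 did not pass, the same numbers when adjusted over the list alone. BAX, a pore former of the mitochondrial outer membrane, rose by 1.36 (SE 0.12), and BID, which activates it, fell by 0.31 (SE 0.07), although its probe sets of the kind made for a single transcript gave 0.03. The list had an adjusted p = 0.0137 in camera, adjusted p = 0.545 with an estimated correlation, and 0.0952 without the 2 members it shares with the p53 list, an alternative chosen after seeing the data. Its call was lost without Ara-C replicate 1 (adjusted p = 0.0625), and 4 members rose without that array or without untreated replicate 3. Of 23 cytarabine uptake and metabolism genes, 3 rose, also when adjusted over the list alone: RRM2B, the p53-induced ribonucleotide reductase subunit (1.5, SE 0.11), its S phase counterpart RRM2 (0.58) and SAMHD1, which breaks down the active form of Ara-C (0.37). That list did not pass in camera (adjusted p = 0.546) and passed in fry, which asks whether the members move one way on balance (adjusted p = 0.0229). Without RRM2B, which it shares with the p53 list, it had a median of 0.01 and a camera adjusted p = 0.895.

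The cell cycle lists moved apart. Of 55 measured G2 and mitosis genes, 8 fell and 47 did not pass, and adjusted over the list alone 9 fell. PLK1, a mitotic kinase, fell by 0.48 (SE 0.12) and CDC20, which activates the anaphase-promoting complex, fell by 0.45 (SE 0.12). The list's median was -0.16, with a camera adjusted p = 2.80e-04 and an adjusted p = 0.46 with an estimated correlation. Without untreated replicate 2, untreated replicate 3 or Ara-C replicate 2, 2 members fell. Without Ara-C replicate 1 or 3, 4 fell, and without untreated replicate 1, 13. MKI67, the proliferation marker Ki-67, changed by -0.36 (SE 0.14), which did not pass in limma (adjusted p = 0.136). The change of MKI67 was -0.17 without untreated replicate 1 and -0.45 without untreated replicate 2. Of 49 DNA replication and S phase genes, 7 rose, 1 fell and 41 did not pass, and adjusted over the list alone 15 rose and 1 fell. CCNE2 and CCNE1, the E-type cyclins of the G1 to S transition, rose by 0.90 (SE 0.08) and 0.79 (SE 0.09), and E2F1, a transcription factor of that transition, fell by 0.34 (SE 0.08). CCNE1 and E2F1 each passed on 1 of 2 probe sets, the others giving -0.06 and -0.16. This list's median was 0.10, with a camera adjusted p = 0.00228 and an adjusted p = 0.681 with an estimated correlation. It did not pass without untreated replicate 3 (adjusted p = 0.0831). With a variance trend and robust moderation 18 mitosis genes fell and 3 rose, and 17 S phase genes rose. Without the dimmer probe sets 13 mitosis genes fell and 2 rose, and 14 S phase genes rose.

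Genes of growth were lower where they changed. Of 29 measured MYC and ribosome biogenesis genes, 11 fell and 18 did not pass, and 14 fell when adjusted over the list alone. MYC itself fell from a log2 signal of 11.61 ± 0.10 to 10.92 ± 0.07 (SD, n = 3 arrays each), a change of -0.69 (SE 0.08). The median of the list was -0.23, with a camera adjusted p = 9.51e-08 and an adjusted p = 0.421 with an estimated correlation. The number that fell was 4 without untreated replicate 2, 7 without untreated replicate 3, and 6 without Ara-C replicate 2 or 3. Among 50 measured ribosomal protein genes, 0 passed in limma and 1 had an unadjusted p under 0.05 (list median -0.02, camera adjusted p = 0.423).

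**Figure D2:**
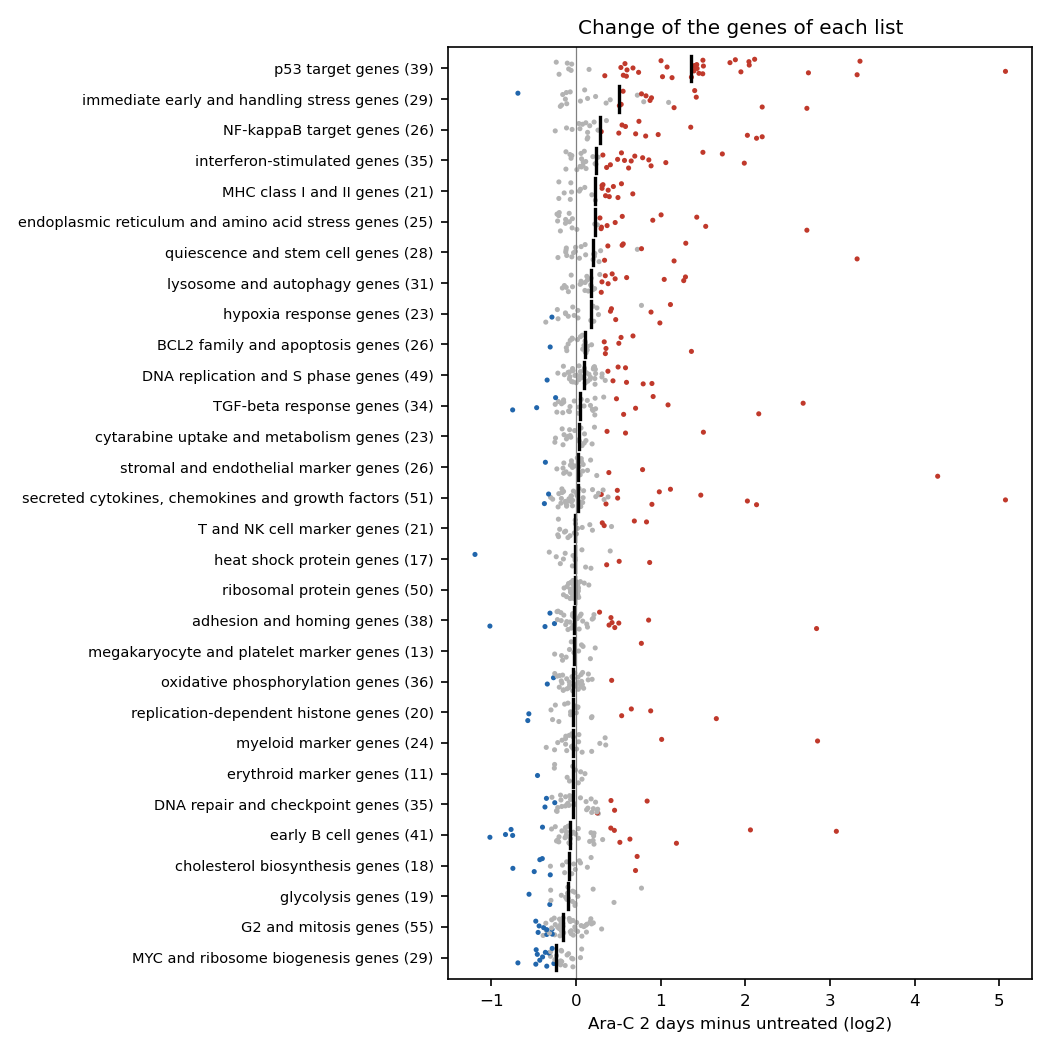
Change of every measured gene of the 30 lists (Ara-C 2 days minus untreated, log2), with a black bar at the median of each list, red and blue points for members that passed as higher or lower in limma, and the number measured in brackets. p53 target genes have the highest median (1.36) and the MYC and ribosome biogenesis genes the lowest (-0.23).

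Some interferon-stimulated, NF-kappaB target and MHC genes rose. Of 35 measured interferon-stimulated genes, 16 rose and 19 did not pass, and adjusted over the list alone 17 rose. IFIT2, an antiviral protein that binds foreign RNA, rose by 1.99 (SE 0.08). The list's median was 0.24, with a camera adjusted p = 1.28e-08 and an adjusted p = 0.340 with an estimated correlation. Of 26 NF-kappaB target genes, 12 rose and 14 did not pass, with 13 rising when adjusted over the list alone. CD69, an early activation marker of lymphocytes, rose by 2.20 (SE 0.39) from untreated values that spread widely (SD 0.99, n = 3 arrays), and its call was lost in limma with a variance trend and robust moderation (adjusted p = 0.0662). CCL4, a chemokine for myeloid and T cells, rose by 2.13 (SE 0.14). The median was 0.28, with a camera adjusted p = 1.52e-07 and an adjusted p = 0.181 with an estimated correlation. Of 21 MHC class I and II genes, 10 rose and 11 did not pass, with 11 rising when adjusted over the list alone. HLA-DOA, which tunes the loading of class II molecules, rose by 0.67 (SE 0.09), on 1 of its 5 probe sets. This list had a median of 0.23, a camera adjusted p = 0.00105 and an adjusted p = 0.340 with an estimated correlation. HLA genes are close in sequence, so probes of 1 can bind transcripts of another. The number of MHC genes that rose was 6 without untreated replicate 2, untreated replicate 3 or Ara-C replicate 1, and 5 without Ara-C replicate 2.

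Some immediate early, endoplasmic reticulum stress, lysosome and quiescence genes rose as well. Of 29 measured immediate early and handling stress genes, 12 rose, 1 fell and 16 did not pass, and adjusted over the list alone 15 rose and 1 fell. ATF3, a stress-induced transcription factor, rose by 2.73 (SE 0.21), on 2 of its 3 probe sets, the lowest giving -0.03. The member that fell was MYC. The list's median was 0.51, with a camera adjusted p = 7.11e-05 and an adjusted p = 0.402 with an estimated correlation. Its mean, taken against the untreated mean, was 0.14, 0.10 and -0.24 on untreated replicates 1 to 3. On Ara-C replicates 1 to 3 it was 0.62, 0.53 and 0.52. Whether handling differed between the groups was not tested. Of 25 endoplasmic reticulum and amino acid stress genes, 11 rose and 14 did not pass, and adjusted over the list alone 12 rose and 4 fell. That list had a camera adjusted p = 0.0161, an adjusted p = 0.522 with an estimated correlation, and 0.0575 without the member it shares with the p53 list. Its call was also lost without the dimmer probe sets (adjusted p = 0.0894) and with probe sets of the kind made for a single transcript (0.0817), where its median was 0.01 against 0.22. Its rising members numbered 6 and 5 without Ara-C replicates 1 and 2. Of 31 lysosome and autophagy genes, 10 rose and 21 did not pass, with 11 rising when adjusted over the list alone. SQSTM1, the autophagy receptor p62, rose by 1.29 (SE 0.08), on 2 of its 5 probe sets, the lowest giving -0.04. The median was 0.18, with a camera adjusted p = 1.96e-05 and an adjusted p = 0.340 with an estimated correlation, and 6 members rose without untreated replicate 3 or without Ara-C replicate 1 or 2. Of 28 quiescence and stem cell genes, 8 rose and 20 did not pass, with 11 rising when adjusted over the list alone. CDKN1A, shared with the p53 list, led them (median 0.20, camera adjusted p = 1.23e-04, adjusted p = 0.181 with an estimated correlation).

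Of the lists closest to the niche, none passed camera, though single members changed. Among 51 measured secreted cytokines, chemokines and growth factors, 11 rose, 2 fell and 38 did not pass, and adjusted over the list alone 12 rose and 3 fell. GDF15 and CCL4 led the rises, and VEGFA, a growth factor for blood vessels, rose by 1.11 (SE 0.12). VEGFA passed on 1 of its 4 probe sets, the lowest giving 0.002. CSF3, the granulocyte growth factor G-CSF, fell by 0.37 (SE 0.08) and MIF, a macrophage cytokine, fell by 0.32 (SE 0.09). The list had a median of 0.02 and a camera adjusted p = 0.109, and limma's fry gave an adjusted p = 6.75e-04. The number that rose was 7 without untreated replicate 2. The falls numbered 1 without untreated replicate 2 or Ara-C replicate 3, and both were lost without untreated replicate 3 or Ara-C replicate 2. Among 34 TGF-beta response genes, 7 rose, 3 fell and 24 did not pass, the same numbers when adjusted over the list alone. SMAD3, which carries the TGF-beta signal to the nucleus, rose by 2.68 (SE 0.09), and BHLHE40, a repressor of the basic helix-loop-helix type, by 2.16 (SE 0.15). SMAD3 passed on 2 of its 4 probe sets and BHLHE40 on 1 of 2, the other giving 0.18. ID3, a target of the BMP branch, fell by 0.75 (SE 0.14), and LDLRAD4, a feedback inhibitor, fell by 0.47 (SE 0.13) but rose by 0.72 on another probe set. TGIF1, a repressor of SMAD signalling, fell by 0.24. TGFB1, the ligand itself, changed by -0.15 (SE 0.12), which did not pass in limma (adjusted p = 0.466). The median of this list was 0.05, with an adjusted p = 0.202 in camera and 0.00846 in fry, and 1 member fell without any of the Ara-C replicates, each left out in turn.

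Among 38 adhesion and homing genes, 8 rose, 4 fell and 26 did not pass, the same numbers when adjusted over the list alone. CCR7, a homing receptor for lymph nodes, rose by 2.84 (SE 0.25), and ITGA6, a laminin receptor subunit, by 0.86 (SE 0.09). CD9, CD58, TLN1 and ESAM fell by 1.02, 0.37, 0.31 and 0.26. CXCR4, the receptor for the marrow chemokine CXCL12, changed by 0.13 (SE 0.08), which did not pass in limma (adjusted p = 0.336). The median was -0.02 and the mean 0.09, with an adjusted p = 0.845 in camera. The number that rose was 3 without untreated replicate 2 or Ara-C replicate 1 or 2, and 5 without untreated replicate 1 or 3. The number that fell was 1 without untreated replicate 2 or Ara-C replicate 2, and 2 without untreated replicate 3 or Ara-C replicate 1 or 3.

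Early B cell genes were split. Of 41 measured, 7 rose, 5 fell and 29 did not pass, and adjusted over the list alone 10 rose and 8 fell. MS4A1 rose by 3.07 (SE 0.32), with all 4 of its probe sets past the threshold. PTPRC, the leukocyte phosphatase CD45, rose by 2.06 (SE 0.09), on 3 of its 5 probe sets. BCL6 (1.19), CD72 (0.64), BLNK (0.52) and SPIB (0.41) rose too. These and MS4A1 and PTPRC were also counted among later B cell genes below, so the list mixes stages. The members that fell were CD9, IGLL1 (-0.83, SE 0.12), RAG1, a recombinase of antigen receptor genes (-0.77), ID3 and TCF3, the E protein that starts the B lineage (-0.40). The median was -0.07 and the mean 0.08, and camera gave an adjusted p = 0.835 in the direction down.

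**Figure D3:**
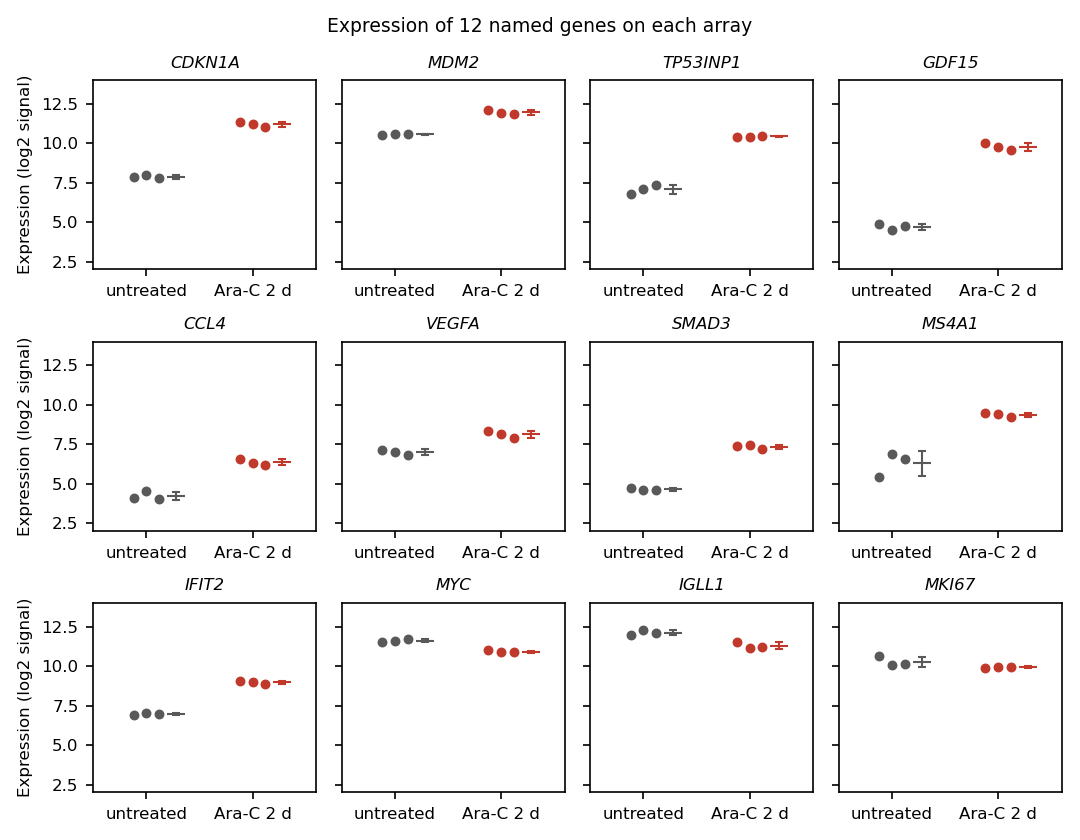
Expression (log2 signal) of 12 named genes on each array, with untreated arrays in grey and Ara-C arrays in red, and a bar for the mean with its SD (n = 3 arrays). For CDKN1A the residual cells lie at 11.18 ± 0.16 against 7.86 ± 0.11, while MKI67, which did not pass, lies at 9.93 ± 0.06 against 10.29 ± 0.32.

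The lists that did not pass and had few changed genes are given here with those genes, which were named after their values were seen where the rule for named genes did not take them. Of 20 replication-dependent histone genes, 4 rose and 2 fell, also when adjusted over the list alone. H2AC6 (1.66, SE 0.15), H2BC21 (0.88), H2BC4 (0.65) and H2BC12 (0.54) rose, while H1-3 and H2BC14 fell by 0.57 and 0.56. Their sequences are so alike that probes cannot always tell them apart (median -0.04, mean 0.08, camera adjusted p = 0.961), and 1 histone gene fell without untreated replicate 1 or 2 or Ara-C replicate 1, 3 fell without untreated replicate 3, and both falls were lost without Ara-C replicate 3. Of 35 DNA repair and checkpoint genes, 4 rose and 3 fell, against 5 and 7 when adjusted over the list alone. RAD51C, of homologous recombination (0.84, SE 0.09), EXO1 (0.45), RAD52 (0.41) and ATR (0.25) rose, and LIG3, a DNA ligase, WRN and RAD17 fell by 0.37, 0.35 and 0.25 (median -0.04, mean 0.02, camera adjusted p = 0.924). RAD51C passed on 1 of its 2 probe sets, the other giving 0.03. 2 of the repair genes rose without untreated replicate 2 or 3 or any Ara-C replicate, each left out in turn. The number that fell was 1 without Ara-C replicate 3, and the falls of all 3 were lost without Ara-C replicate 2. With quantile normalization 3 repair genes rose and 7 fell. Of 23 hypoxia response genes, 6 rose and 1 fell, against 11 and 3 when adjusted over the list alone. VEGFA led the rises, on 1 of its 4 probe sets. ERO1A, an oxidase of the endoplasmic reticulum, fell by 0.29 (list median 0.17, camera adjusted p = 0.0531). The hypoxia list passed without untreated replicate 2 (adjusted p = 0.0339) or Ara-C replicate 3 (adjusted p = 0.0157), and in fry (adjusted p = 0.0229).

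Of 17 heat shock protein genes, 3 rose and 1 fell, against 3 and 2 when adjusted over the list alone. DNAJB4, DNAJB6 and DNAJA1, cochaperones of HSP70, rose by 0.87, 0.51 and 0.36, and HSPB1 fell. HSPB1 read 9.09 on untreated replicate 1 and 10.29 and 10.51 on untreated replicates 2 and 3, against 8.57 to 9.0 in residual cells (list median -0.01, mean 0.01, camera adjusted p = 0.961). Without untreated replicate 1, 3 heat shock genes fell, and without any other single array the fall of HSPB1 was lost and no other member fell. Of 18 cholesterol biosynthesis genes, 2 rose and 5 fell, against 2 and 6 when adjusted over the list alone. TM7SF2 (0.72, SE 0.08) and HSD17B7 (0.70) rose. INSIG1, which holds back the activation of SREBP, fell by 0.75 (SE 0.09), and HMGCS1, SQLE, SREBF2 and DHCR7 fell by 0.49, 0.43, 0.40 and 0.30 (median -0.08, camera adjusted p = 0.215). 3 of these genes fell without Ara-C replicate 1 or 2. Of 36 oxidative phosphorylation genes, NDUFB1 rose by 0.42 while CYC1 and NDUFS1 fell by 0.34 and 0.27, and adjusted over the list alone 1 rose (median -0.04, camera adjusted p = 0.233). The rise of NDUFB1 rested on 1 of its 2 probe sets, the other giving 0.04, and did not pass with the mean of both. Both falls were lost without untreated replicate 2 or 3 or Ara-C replicate 2 or 3, and 1 gene of the list fell without untreated replicate 1 or Ara-C replicate 1. Of 19 glycolysis genes, PFKM, a phosphofructokinase, fell by 0.56 (SE 0.07) and ALDOC by 0.31, and adjusted over the list alone 2 rose and 3 fell (median -0.09, camera adjusted p = 0.174). Without Ara-C replicate 1, 3 glycolysis genes fell, and without any other single array 1 fell, with 2 rises without untreated replicate 1. The list passed with probe sets of the kind made for a single transcript (adjusted p = 0.0465).

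Markers of other cell types that a sort could carry along did not shift as lists. Some were already bright in untreated cells, among them TFRC (11.67), IL7R (11.12) and S100A4 (11.03), and need not mark carried cells. Of 26 stromal and endothelial markers, ACTA2, EMCN (0.79) and COL5A1 (0.39) rose and S100A4 fell by 0.36, while VIM, the brightest at 12.85 in untreated cells, changed by 0.06 (camera adjusted p = 0.669). Of 24 myeloid markers, ITGAM, an integrin of myeloid and NK cells, rose by 2.85 (SE 0.15) on 1 of its 2 probe sets, the other giving 0.06, and LYZ, lysozyme, by 1.01 (SE 0.14) on both of its probe sets (camera adjusted p = 0.930). Of 21 T and NK cell markers, NKG7 (0.83), PRF1 (0.69), IL7R (0.33) and LCK (0.31) rose, 5 when adjusted over the list alone (camera adjusted p = 0.423). 2 of them rose without any of the untreated replicates or without Ara-C replicate 3, each left out in turn. Of 13 megakaryocyte and platelet markers, TREML1 rose by 0.77, and NRGN, the brightest, changed by 0.03 (camera adjusted p = 0.982). Of 11 erythroid markers, HBB, adult beta globin, fell by 0.46 (SE 0.10), while its probe sets of the kind made for a single transcript gave 0.12, and TFRC, the brightest, changed by -0.25 (camera adjusted p = 0.407). Adjusted over each list alone, the stromal, myeloid, megakaryocyte and erythroid counts were the same. In the myeloid, T and NK cell and megakaryocyte lists the median was below 0 (-0.04, -0.01 and -0.03) and the mean above it (0.14, 0.08 and 0.04).

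Several changes of named genes did not pass when 1 array was left out, although their direction stayed. CDC20, PLK1, CYC1, ERO1A, HBB and MIF each lost their call without untreated replicate 2 or 3 or Ara-C replicate 2 or 3. In limma the highest adjusted p over these arrays was 0.143 for CDC20, 0.110 for PLK1, 0.108 for CYC1, 0.0867 for ERO1A, 0.0704 for HBB and 0.148 for MIF. HSPB1 lost its call without any array but untreated replicate 1 (adjusted p up to 0.121 in limma), and IL7R without any but Ara-C replicate 1 (up to 0.102). BID lost it without untreated replicate 2 (0.0964) or any Ara-C replicate (up to 0.0819), and H1-3 without untreated replicate 1 or 2 or Ara-C replicate 1 or 3 (up to 0.0762). E2F1 lost it without untreated replicate 1 or 2 or Ara-C replicate 2 (up to 0.0912), and LDLRAD4 without any Ara-C replicate (up to 0.141). CD58 lost it without untreated replicate 2 or Ara-C replicate 2 (up to 0.0602), CSF3 without untreated replicate 3 or Ara-C replicate 2 (up to 0.0629), and LIG3 without Ara-C replicate 2 or 3 (up to 0.0664).

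Over all 30 lists, 12 passed camera with the preset correlation, 10 up and 2 down. With an estimated correlation 0 passed in limma's camera and 4 had an unadjusted p under 0.05, while 15 passed in fry, which does not compare a list with other genes.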

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

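The tests on the other stromal and myeloid markers and the ratio of rises to falls after rescaling were chosen after the results they bear on were seen. The test of a signal floor among bright genes and the random lists matched on mean signal also weigh patterns found in the results. Such random lists were drawn only for the p53, S phase, mitosis and ribosome biogenesis lists. These tests are therefore not counted as fixed in advance.

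Some signals lay in probe sets outside the comparison of genes. A probe set annotated to CCL3, CCL3L1 and CCL3L3 together, which cannot be assigned to any 1 of these chemokine genes, rose by 3.59 on the log2 scale (SE 0.22), from 4.42 ± 0.49 to 8.01 ± 0.21 (SD, n = 3 arrays), with an adjusted p of 2.81e-05 in limma. A probe set annotated to HBA1 and HBA2 together, the alpha globin genes, had a change of -0.74. Among all 1801 probe sets annotated to several genes, 105 were higher and 60 lower in residual cells. Among the 11721 probe sets without a gene in the annotation table, 325 were higher and 447 lower, while 53 rose and 7 fell by at least 2-fold.

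The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes residual and untreated arrays, so the difference between them widens the spread within its groups. Low counts of genes in those splits thus say little. For genes, 1 of the 10 splits gave as many as the real one, which was the real one itself, with 2710 genes against at most 0 in the others (limma, where these others had 193 to 899 genes at an unadjusted p under 0.05). For probe sets the real split gave 5091 and the highest other 0 (639 to 2779 at an unadjusted p under 0.05), again with 1 split as large. For gene lists the real split gave 12 and the others 1 to 11, with 1 split as large.

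The rise of ACTA2 (4.27) and of ITGAM (2.85), markers of other cell types, is the first pattern weighed. Human stromal cells among the sorted cells would bring their other abundant transcripts, but the 25 other stromal and endothelial members had a median change of 0.0147 (SD 0.22, highest 0.79), with COL1A1 at 0.05 and SPARC at 0.06. For human myeloid cells, the 23 other members had a median change of -0.0393 (SD 0.28), with S100A8 at -0.08, S100A9 at 0.03 and TYROBP at -0.05, and LYZ highest at 1.01. Both values argue against such human cells, but the host is a mouse, so carried cells would be mouse cells. The values say little about these, which the sort on GFP should remove. Where the signal of members such as VIM and LYZ comes from was not tested. Binding of another transcript to the single probe set behind each rise, mouse RNA, which binds human probes unevenly, and a change in the leukemia cells under Ara-C all stay open.

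The excess of rises over falls of at least 2-fold, 257 against 6 (2 to 10 falls with 1 array left out), is the second. A floor of the array signal hides falls of dim genes, yet among the 5299 genes with an untreated mean above 8 there were 30 such rises and 4 falls (exact two-sided binomial p = 6.16e-06, which treats genes as independent). These counts argue against the floor as the whole cause. It may still add to the excess, since 227 of the rises came from the 14476 genes at or below 8. An offset between the arrays of the groups would shrink under quantile normalization, and the ratio of rises to falls was 31.5 after it, with 2909 genes passing. The deposited values show no uniform offset, with array medians at 4.82 to 4.87 and upper quartiles at 6.81 to 6.90. Quantile normalization and centring therefore moved too little to decide. How the values had been normalized before is not known here. A true excess of induced genes under Ara-C is a hypothesis that stays open beside a change in the total RNA per cell, which the arrays cannot show. Residual cells are those that remained, so the design cannot tell genes changed by Ara-C from loss of cells that had other levels.

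The opposite shifts of the S phase list against the mitosis and ribosome biogenesis lists, with the p53 list for comparison, are the third. Were they a trend of the change with signal level, random lists matched on mean signal would shift as much. Among 10000 such lists, the median of p53 target genes lay at percentile 100, that of S phase genes at 99.8, that of G2 and mitosis genes at 0 and that of MYC and ribosome biogenesis genes at 0, which argues against that trend. Correlated expression within the list stays open for the S phase, mitosis and ribosome biogenesis lists (camera adjusted p from 0.421 to 0.681 with an estimated correlation). The p53 list did not pass with it either (0.192). Its mean, however, was 1.13 to 1.36 on the Ara-C arrays against -0.02 to 0.03 on the untreated ones, far beyond its spread between arrays. The other means did not overlap between the groups either, with smaller gaps. They were 0.12 to 0.17 on Ara-C arrays against -0.07 to 0.09 on untreated ones for S phase. For mitosis they were -0.15 to -0.12 against -0.07 to 0.04, and for ribosome biogenesis -0.32 to -0.18 against -0.05 to 0.05. A change of cell cycle phase under Ara-C also stays open, untested here, and 41 of 49 S phase genes did not pass, MCM2 (-0.07) and MCM7 (-0.14) among them.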

How the results depend on the processing

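Most results kept their direction and their side of the threshold. Of 871 alternatives computed for the 67 named genes, 794 stayed on the same side, and 46 of the genes did so in all of theirs. The number of genes past the threshold was 263 with a change of at least 2-fold required as well, 1269 at an adjusted p under 0.01, and between 2467 and 3630 under the other planned settings apart from the block. Leaving out 1 array at a time gave 1589 to 2382 genes, lowest without Ara-C replicate 2 (1589) and untreated replicate 2 (1662), and 2535 to 3924 probe sets, with 2535 and 2537 for the same arrays. Smaller groups are 1 reason for fewer calls. Why these arrays mattered most was not tested.

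With an estimated correlation, 0 of 30 lists passed in camera (4 at an unadjusted p under 0.05), against 12 with the preset one, and the adjusted p was 0.192 for p53 target genes, 0.681 for S phase genes and 0.46 for G2 and mitosis genes. With fry, which asks another question, the S phase list no longer passed (0.0650), while the TGF-beta (0.00846), secreted factor (6.75e-04), cytarabine (0.0229) and hypoxia (0.0229) lists did. Leaving out 1 array at a time, the S phase list had an adjusted p between 9.75e-06 and 0.0831, highest without untreated replicate 3. The cause was not tested.

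Among named genes that passed, direction turned in 4, all when probe sets ending in _x_at or _s_at were set aside, so that another probe set stood for the gene. The change became 0.0254 for BID, -0.0244 for GDF15, 0.12 for HBB and 0.72 for LDLRAD4. NRGN, which did not pass, changed by 0.0298 and turned to -0.00603 with quantile normalization, -0.0385 without untreated replicate 3 and -0.0281 without Ara-C replicate 1, none of which passed. Which probe set is right was not tested.

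The same replicate numbers occur in both groups, but they share only a number. Deviations from the group means correlated at -0.05, -0.05 and 0.15 for numbers 1 to 3, and the pairs with the highest correlation were not always of 1 number (0.24 for untreated replicate 2 with Ara-C replicate 1). With a replicate block, 2310 genes passed, 2193 of them shared, with 4110 probe sets and 13 lists (hypoxia added, adjusted p = 0.0390), 4 mitosis genes fell, and 5 named genes no longer passed. The genes that lost their call were CDC20 (adjusted p = 0.0743 in limma), CYC1 (0.0619), ERO1A (0.0629), MIF (0.0859) and PLK1 (0.0544). A pseudocount gave no value, since the deposited values are already logarithms. Signal over background is not known here, so changes of dim genes are the least certain.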

Other observations

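The lists of later B cell genes and of mitochondrial ribosomal proteins were made after some of their members had been seen, and the tests on mitochondrial ribosomal proteins, on globins and on the S phase minus mitosis difference were chosen after the results were seen. The test on later B cell genes was written before the members it uses were looked at.

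Beyond the early B cell list, several genes of later B cell stages were among the strong rises. FCRL5, an Fc receptor-like protein of mature B cells, rose by 2.74 (SE 0.10), IL21R, the receptor for a cytokine of B cell help, by 2.99 (SE 0.17), and CD80, a ligand for T cell costimulation, by 1.98 (SE 0.11). These were seen first and cannot test the idea. Of 35 further genes of this kind that were measured, 7 rose and 2 fell, with a median change of 0.08. TNFRSF9 (1.68), BANK1 (1.49), FCRLA (1.15), LY9 (1.04) and JCHAIN (0.90) were the largest rises, and IGHD fell by 0.54 and CD48 by 0.48. In camera these 35 genes passed narrowly, with p = 0.0492, and p = 0.114 with an estimated correlation. A hypothesis is that residual cells may carry more transcripts of later or activated B cells, but most members did not change, and genes such as FCER2 (0.00) and CR2 (-0.15) did not pass.

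Of 75 measured MRPL and MRPS genes, 14 fell and 2 rose, with a median of -0.10. MRPS28, MRPL48 and MRPS34 fell by 0.53, 0.47 and 0.47. Camera gave p = 3.45e-04, and p = 0.481 with an estimated correlation, but the list was made after the scan below had shown the fall, so this p restates it. In a scan of 394 tests of gene families by symbol, 10 of 50 MRPL genes were lower (Fisher's exact test, one-sided, adjusted p = 0.00839), and 10 of 22 HLA genes were higher (adjusted p = 0.00474). The scan took every symbol that starts with MRPL, while the list of 75 took only plain numbered symbols, so their counts differ. The cytosolic ribosomal proteins gave 0 calls of 50 in limma, with 1 at an unadjusted p under 0.05.

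HBE1, at a log2 signal of 10.68 in untreated cells, fell by 2.63, and HBB fell by 0.46. Erythroid cells among the sorted untreated cells would bring other erythroid transcripts, but the 9 erythroid markers that are not globins had a median change of -0.0402 (SD 0.12), with ALAS2 at -0.08 and AHSP at 0.03. Of these, 8 lay at or below a log2 signal of 8 in untreated cells, most near the low end, where they could hardly fall, so the value does not decide. HBE1 passed on 1 of its 2 probe sets, the other giving 0.06, and globin genes share sequence, so binding of related transcripts stays open beside a change in the leukemia cells. Erythroid cells, which the sort on GFP should remove, are not excluded. They would be cells of the mouse host, whose RNA binds human probes unevenly. HBB read 6.32, AHSP 5.26 and ALAS2 4.38 in untreated cells. Signals of different probe sets cannot be compared as amounts, so these levels do not decide either.

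The mean of the S phase list minus that of the mitosis list, each taken against the untreated mean, was 0.25, 0.26 and 0.29 on the Ara-C arrays and 0.16, -0.06 and -0.10 on the untreated ones (log2). The lowest Ara-C array lay 0.0914 above the highest untreated one, untreated replicate 1. The group means differed by 0.27, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. Both lists were known to move apart, so this describes the arrays and tests nothing further. In the untreated cells 1 array lay closer to the residual cells than to the other untreated ones on this measure.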
